A study of Mus musculus with 64 samples.

How the data were processed

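RNA from mouse medulloblastoma cells and from sorted cerebellar cells was measured on 64 Affymetrix mouse expression arrays, 1 RNA sample per array. Per the labels, 51 arrays were prepared with a one-cycle labelling kit and 13 with the Affyexpress kit. The deposited table holds log2 signal values for 45101 probe sets, which the authors made with RMA in Partek 6.5, per their processing notes. The values ran from 1.43 to 14.9, and array medians ran from 5.42 to 5.60. Arrays give no read depth, and their number limits the precision. The labels do not say which arrays come from separate animals, so the p-values measure the spread between arrays.

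The 64 arrays were placed in 11 groups from their labels. The one-cycle groups were 8 spontaneous Shh-type tumours of Cdkn2c-null, Trp53-floxed, Nestin-Cre mice, 8 spontaneous Shh-type tumours of Cdkn2c-null, Ptch1-heterozygous mice, 14 tumours of cells with a mouse Myc vector marked by mRFP, 3 of cells with a human MYC vector marked by GFP, 4 of cells with a Mycn vector marked by mRFP, 7 of cells with a Mycn vector marked by GFP, 3 Wnt-type tumours, and 4 samples of control cells. The Affyexpress groups were 5 GFP-positive and 5 GFP-negative fractions sorted from Myc tumours, and 3 repeats of mouse Myc vector tumours. Replicate numbers only name the arrays, in their order within a group. No paired analysis was possible because the labels link no GFP-positive array to a GFP-negative one, so whether these fractions come from the same tumours is not known.

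Gene symbols of the platform table were brought up to date through their Entrez Gene identifiers for 34754 of the 34958 probe sets that carry exactly 1 symbol. The 932 probe sets with several symbols and the 9211 without a symbol were left out. Each gene was represented by its probe set with the highest mean over the arrays of a fit, which left 18194 genes, of which 9012 had more than 1 probe set. No genes were removed for low signal. Trp53 was not analysed here.

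Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), without covariates. All 51 one-cycle arrays were fitted together as 8 groups, which leaves 43 residual degrees of freedom per gene. A class mean was the mean of its arrays over both models. Wnt tumours were compared with the unweighted mean of the Shh, Myc and Mycn class means. The 10 sorted arrays were fitted alone. P-values were adjusted by Benjamini and Hochberg over all genes of a comparison, and a gene was called when its adjusted p was under 0.05 and its log2 difference was at least 1 in size, which is a fold of 2. Only called genes are said to have risen or fallen. Values are given as log2 difference ± standard error.

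24 gene lists with 308 members, of which 279 were measured, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The lists covered SHH pathway and target genes, WNT pathway and target genes, ribosome biogenesis and MYC target genes, glycolysis, cell cycle, p53 target, Hox, interferon response, dissociation and stress, sex-linked, pluripotency and oncofetal, photoreceptor, granule neuron lineage, neuronal differentiation and neural stem cell genes. They also covered markers of microglia and macrophages, lymphocytes, endothelial and mural cells, fibroblasts and meninges, astrocytes, the oligodendrocyte lineage, cerebellar GABAergic neurons, choroid plexus and ependyma, and erythroid cells. For each list the number of members called is given over all genes and, where it differs, adjusted over the list alone.

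The groups, the tests, the threshold, the lists, the genes to name and the processing alternatives were fixed before the data were examined, except where a choice is said to have been made later. The genes to name were the 10 called genes with the largest rise and the 10 with the largest fall in each of the main comparisons (Myc with Shh, Myc with Mycn, Mycn with Shh, Wnt with the other tumours, Myc with control, both Shh models, GFP-positive with GFP-negative) and 5 each way in the others, clone names left out. To these were added Myc, Mycn, Cdkn2c, Ptch1, Ctnnb1, Atoh1, Gli1 and Axin2 everywhere, and up to 4 members of each list with the largest differences.

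The procedure was tested on simulated data with 100 genes changed 3-fold and 100 changed 6-fold. Noise was drawn independently for each gene, with the same spread in every group. The real groups differed in spread, so the shares below need not hold for them. With the group sizes of the Myc and Shh comparison, 99% of the 3-fold changes and all of the 6-fold changes were called with 0 false calls. With the sizes of the Myc and control comparison it was 95% and 97% with 3 false calls, with those of the Wnt comparison 93% and 99% with 2, with those of the Mycn vectors 88% and 97% with 2, and with those of the sorted fractions 84% and 94% with 8.

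The alternatives tried were a filter on dim probe sets (group mean of at least 6 in 1 group or more), the mean of a gene's probe sets, the most variable probe set, quantile normalization, median centring, a trended and robust variance, array weights, the adjusted p alone, fits of only the groups compared, single models or vectors of a class, equal weights for the models of a class, repeats averaged with their originals, and each array left out in turn in groups of up to 5 arrays. The alternatives added later leave out arrays that stood apart, 1 probe set of Mycn, or each array in turn in groups of more than 5, or match Myc and Mycn tumours by marker and mouse line. The 5 arrays that stand apart are replicates 3, 8 and 14 of the mouse Myc tumours and 2 Mycn tumours. The latter are replicate 2 with the mRFP vector and replicate 3 with the GFP vector. Each comparison was repeated on 100 random splits of its arrays into groups of the same sizes, the real split included.

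The comparison of the kits was left out of the results. In the deposited table the mean of the 3 repeats equals the mean of their 3 originals within 1e-04 in all 45101 probe sets (largest difference 3.33e-06), so a difference between the kits cannot appear. For the same reason the tests between groups compared Affyexpress arrays only with each other. Values of single arrays from both kits are set side by side in the closing section where it says so.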

Results

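The 64 arrays covered 4 kinds of mouse medulloblastoma, a malignant tumour of the cerebellum, and control cells sorted from the cerebellum at postnatal day 6. Shh-type tumours (16 arrays) and Wnt-type tumours (3 arrays) arose spontaneously in engineered mice. Myc tumours (17 arrays) and Mycn tumours (11 arrays) grew in nude mice from injected cerebellar cells. These cells lacked Cdkn2c and Trp53 and carried a Myc or Mycn vector. The control cells (4 arrays) also lacked Cdkn2c and Trp53 and were sorted for GFP driven by Atoh1, also called Math1, a transcription factor of granule neuron precursors. The other 13 arrays were 5 GFP-positive and 5 GFP-negative fractions of Myc tumours and 3 repeats of Myc tumours, all made with another labelling kit. Tumour cells were dissociated and purified on Percoll before RNA extraction. Among the 51 one-cycle arrays the first principal component held 28.9% of the variance and the second 16.7%. The signal at the 3' end minus that at the 5' end of beta-actin, a sign of RNA quality, differed between the one-cycle groups. It averaged 1.91 in Wnt tumours, 1.24 in the Ptch1-heterozygous Shh model and 1.18 in control cells, against 0.71 in the Trp53-floxed Shh model and 0.569 to 0.775 in the Myc and Mycn groups.

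**Figure D1:**
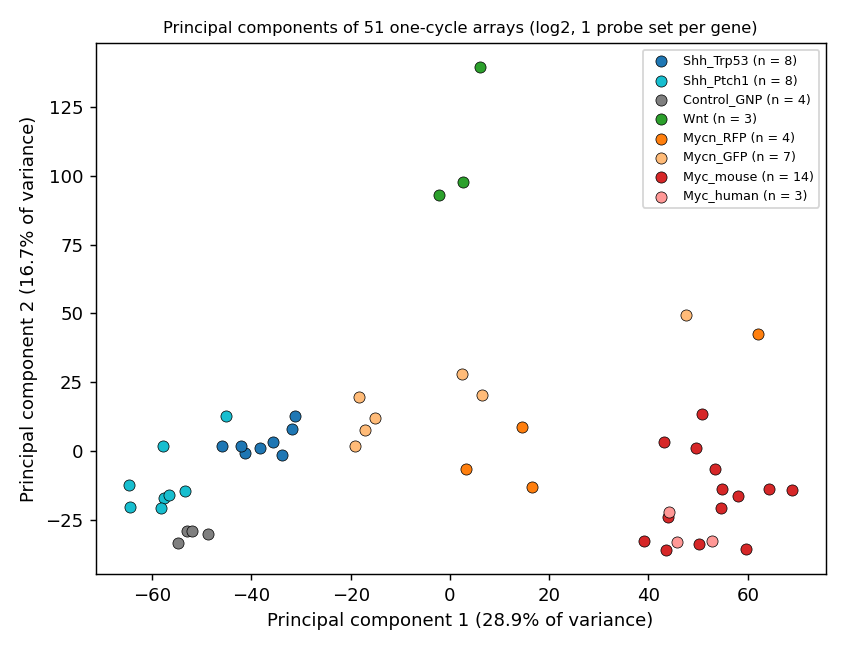
Principal components of the 51 one-cycle arrays, with the first component (28.9% of the variance) on the horizontal axis and the second (16.7%) on the vertical axis; each point is an array and each colour a group. Myc tumours lie to the right, Shh-type tumours and control cells to the left, and Wnt tumours at the top.

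The signals of the altered genes were first compared between groups. Myc was at 10.70 ± 0.34 (SD, n = 14) in tumours with the mouse Myc vector and 6.47 ± 0.61 (SD, n = 11) in Mycn tumours. It was at 8.18 ± 0.56 (SD, n = 8) in the Trp53-floxed Shh model, 7.82 ± 0.86 (SD, n = 8) in the Ptch1-heterozygous one and 7.22 ± 0.10 (SD, n = 4) in control cells. In the 3 tumours labelled with the human MYC vector it was at 5.49, 5.20 and 10.34. The values of 5.49 and 5.20 are below control cells. The mouse probe set is therefore not read as the level of MYC from the human vector. The probe sets of Mycn differed from each other. The one with the highest mean signal over the arrays, which stands for Mycn in the fits, was at 13.59 ± 0.24 (SD, n = 17) in Myc tumours and 13.16 ± 0.37 (SD, n = 11) in Mycn tumours, against 5.73 ± 0.26 (SD, n = 16) in Shh-type tumours. Another probe set of Mycn was at 11.98 ± 0.66 in Shh-type tumours, 9.65 ± 2.23 in Mycn tumours and 6.09 ± 0.71 in Myc tumours. The remaining one was at 7.61 ± 0.74 in Shh-type tumours, 10.17 ± 1.21 in Mycn tumours and 5.77 ± 0.29 in Myc tumours. The vectors of the Myc tumours are not labelled as carrying Mycn. Values of the strongest probe set are therefore not read as the level of Mycn. Cdkn2c, an inhibitor of cyclin-dependent kinases, was at 5.17 ± 0.14 (SD, n = 8) in the Trp53-floxed Shh model and 8.63 ± 0.58 (SD, n = 3) in Wnt tumours, whose labels name no Cdkn2c allele. The libraries labelled replicates 2 and 3 of the Ptch1-heterozygous, Cdkn2c-null model had Cdkn2c at 8.36 and 8.33.

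**Figure D2:**
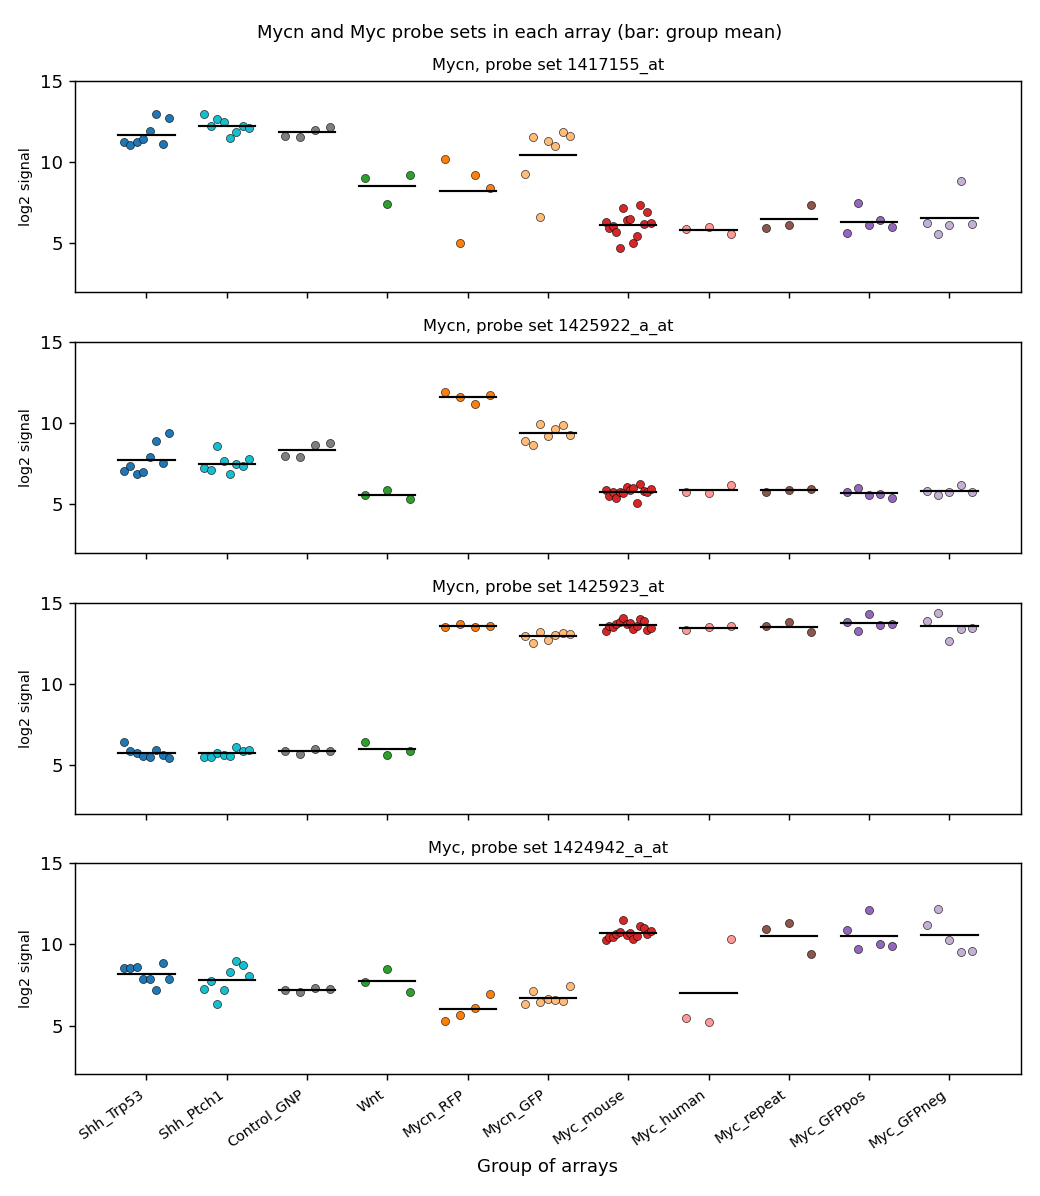
Log2 signal of 3 probe sets of Mycn and 1 of Myc (vertical axis) by group (horizontal axis); points are arrays and bars are group means. The third Mycn panel averages 13.59 in Myc tumours and 5.73 in Shh-type tumours, and the first averages 6.09 and 11.98.

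Myc tumours (n = 17) were compared with Shh-type tumours (n = 16). The Myc tumours grew in nude mice from injected cells, while the Shh-type tumours arose spontaneously. The Ptch1-heterozygous model is also not labelled as lacking Trp53. Driver and growth in nude mice therefore cannot be told apart here. Genes of the granule neuron lineage fell: Atoh1 differed by −5.23 ± 0.44 and Barhl1, a homeobox gene of granule neuron precursors, by −5.20 ± 0.32. In all, 9 of 14 measured members of this list fell and 0 rose (adjusted p = 7.67e-06, and adjusted p = 0.223 with an estimated correlation). SHH pathway genes fell as well, with 7 of 16 lower, among them Gli1, a transcription factor and target of the pathway (−5.04 ± 0.34), Sfrp1, a secreted WNT antagonist (−5.96 ± 0.44), and Boc, a coreceptor (−4.02 ± 0.30). The 1 member that rose was Mycn, through the probe set that was high with every vector. The SHH list had an adjusted p of 0.00376, and adjusted p = 0.352 with an estimated correlation. Glycolysis genes rose in 9 of 13 cases, including Pdk1, a kinase that inhibits pyruvate dehydrogenase (3.99 ± 0.20), and Tpi1, triosephosphate isomerase (2.47 ± 0.16). The adjusted p was 3.35e-06, and adjusted p = 0.115 with an estimated correlation. Among ribosome biogenesis and MYC target genes 8 of 22 rose and 0 fell, with Nop16 at 2.33 ± 0.13 and Srm, spermidine synthase, at 2.19 ± 0.10 (adjusted p = 1.89e-12, and adjusted p = 0.0651 with an estimated correlation). Myc itself rose by 2.04 ± 0.28. Other large rises were those of Ptger3, a prostaglandin E receptor (6.26 ± 0.29), Tuba4a, an alpha tubulin (5.53 ± 0.21), and Igfbp2, an insulin-like growth factor binding protein (4.73 ± 0.35). Large falls included Ntrk3, the neurotrophin-3 receptor (−5.92 ± 0.32). Of the 19 cell cycle genes 0 were called by limma (adjusted p = 0.987 for the list). Fibroblast and meningeal markers moved both ways, 5 of 9 higher (Col3a1, a collagen, 2.84 ± 0.50) and 1 lower (Pdgfra, −3.54 ± 0.40), with an adjusted p of 0.439. Limma called 2264 genes, 1180 higher and 1084 lower in Myc tumours. With equal weights for the vectors the difference of Myc was 0.85, under the size needed for a call. That weighting counts the human MYC tumours more, where the mouse probe set is not read as the level of the vector's MYC.

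Myc and Mycn tumours (n = 11) started from cells with the same lost genes, but marker and mouse line are unbalanced between them: 14 of 17 Myc tumours carry mRFP vectors in Math1-GFP cells, and 7 of 11 Mycn tumours GFP vectors in cells without Math1-GFP. Sex may be unbalanced as well, since Y-linked Uty was lower in Myc tumours (−1.69 ± 0.42). It was the 1 of 4 sex-linked genes called (camera adjusted p = 0.330 for the list). Atoh1 was lower in Myc tumours by −4.63 ± 0.49, Barhl1 by −3.65 ± 0.36 and Gli1 by −3.44 ± 0.38. Among the Mycn tumours Gli1 was at 4.39 in mRFP replicate 2 and 3.92 in GFP replicate 3, against 6.58 to 9.48 in the others. In those 2 arrays Atoh1 was at 6.66 and 4.95. The SHH list had 7 of 16 members lower and 0 higher (adjusted p = 1.18e-05, and adjusted p = 0.0962 with an estimated correlation). The granule list had 4 of 14 lower and 1 higher (adjusted p = 0.00163, and adjusted p = 0.481 with an estimated correlation). Of 13 neural stem cell genes 4 fell, among them Hes1, a NOTCH target (−1.68 ± 0.25), Id3, an inhibitor of differentiation (−1.66 ± 0.36), Fabp7, a radial glia protein (−3.07 ± 0.63), and Sox2, a stem cell transcription factor (−2.51 ± 0.64). The list had adjusted p = 0.00292, and adjusted p = 0.231 with an estimated correlation. Beside it astrocyte markers were lower (1 of 7, S100b, a calcium-binding protein, −1.99 ± 0.55; adjusted p = 0.0259, and adjusted p = 0.481 with an estimated correlation), as were dissociation and stress genes (3 of 12; adjusted p = 0.0447, and adjusted p = 0.665 with an estimated correlation). Myc rose by 3.58 ± 0.31, Fgf15, a fibroblast growth factor, by 4.55 ± 0.15, Ptger3 by 5.40 ± 0.32 and Umodl1 by 5.46 ± 0.27. Ribosome biogenesis and MYC target genes were higher in Myc tumours as a list (2 of 22 called, Rrp12, a nucleolar protein, 1.37 ± 0.17; adjusted p = 3.89e-10, and adjusted p = 0.0962 with an estimated correlation). Interferon response genes were lower in Myc tumours (4 of 11, 5 adjusted over the list alone; Oasl2 −2.43 ± 0.58; adjusted p = 0.000424, and adjusted p = 0.519 with an estimated correlation). Markers of other cells were lower beside them: 5 of 9 fibroblast markers (Dcn, decorin, −2.17 ± 0.51; adjusted p = 0.00911, and adjusted p = 0.534 with an estimated correlation). Microglia and macrophage markers were lower as a list (2 of 15; adjusted p = 0.00268, and adjusted p = 0.603 with an estimated correlation). In all 998 genes were called, 392 higher and 606 lower in Myc tumours. With the 4 mRFP-vector tumours alone on the Mycn side 440 genes were called. With the mRFP vectors of Math1-GFP cells on both sides 396 genes were called, without Fabp7 (−1.79), Sox2 (−1.75), Id3 (−1.26), Rrp12 (0.73), Oasl2 (−1.39), Dcn (−1.13) and S100b (−0.62), and the microglia (adjusted p = 0.806), fibroblast (adjusted p = 0.324) and astrocyte lists (adjusted p = 0.500) did not pass. With the GFP vectors on both sides Myc was not called (0.28), and the stress list did not pass (adjusted p = 0.0934). The Myc side then holds only human MYC tumours, where the mouse probe set is not read as the level of the vector's MYC. With the mRFP-vector tumours alone on the Mycn side Fabp7 (−1.71), Sox2 (−1.99), Rrp12 (0.78), Oasl2 (−1.50) and Dcn (−1.41) were not called, and the microglia list (adjusted p = 0.563), the fibroblast list (adjusted p = 0.0659) and the astrocyte list (adjusted p = 0.370, S100b −0.74) did not pass. With the filter on dim probe sets these lists had adjusted p = 0.0533, 0.0661 and 0.133, and with the mouse Myc vector alone the fibroblast list had adjusted p = 0.0502. The stress list did not pass with that filter (adjusted p = 0.226), with the mouse Myc vector alone (adjusted p = 0.0803) or with the Mycn GFP vector alone (adjusted p = 0.269). Nor did it pass (adjusted p = 0.0503 to 0.101) when 1 array was left out, be it replicate 2, 5, 6, 8, 10, 12 or 13 of the mouse Myc tumours, 1 or 3 of the human MYC tumours, 2, 3 or 4 of the Mycn mRFP tumours, 5, 6 or 7 of the Mycn GFP tumours, or the Wnt array with low Axin2.

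Mycn tumours were then compared with Shh-type tumours. Here too driver and growth in nude mice differ together. Atoh1 was at 9.92 ± 2.17 (SD, n = 11) in Mycn tumours and 10.52 ± 0.96 (SD, n = 16) in Shh-type tumours, a difference of −0.60 ± 0.50 that was not called, and Gli1 fell by −1.60 ± 0.38. Granule lineage genes were lower as a list, with 5 of 14 called (Barhl1 −1.55 ± 0.36; adjusted p = 0.000355, and adjusted p = 0.343 with an estimated correlation). Of 15 neuronal differentiation genes 9 fell, such as Cplx2, a complexin of synapses (−1.30 ± 0.19; adjusted p = 9.58e-05, and adjusted p = 0.387 with an estimated correlation). The mean of this list was 5.68 in replicate 2 of the mRFP tumours and 6.505 in replicate 3 of the GFP tumours, against 7.92 to 9.09 in the 9 other Mycn tumours. Without the 5 arrays that stand apart, these included, 1 of the 15 was called (adjusted p = 0.00447), and with array weights 3. Glycolysis genes rose in 8 of 13 cases, with Aldoc, aldolase C, at 2.44 ± 0.52 and Pdk1 at 2.07 ± 0.22. This list passed with both correlations (adjusted p = 9.61e-09, and adjusted p = 0.048 with an estimated correlation). The p53 target list was lower with both as well (2 of 12 called, Cdkn1a, a cell cycle inhibitor, −1.59 ± 0.21 and Eda2r −1.37 ± 0.26; adjusted p = 0.0036, and adjusted p = 0.048 with an estimated correlation). Ribosome biogenesis and MYC target genes were higher (3 of 22, Srm 1.42 ± 0.11; adjusted p = 3.6e-09, and adjusted p = 0.0737 with an estimated correlation), while Myc fell by −1.54 ± 0.31. The largest rises included those of Postn, periostin (4.04 ± 0.53), Col3a1 (3.99 ± 0.57) and Mgp, matrix Gla protein (3.82 ± 0.47). Fibroblast and meningeal markers rose in 7 of 9 cases and fell in 1 (adjusted p = 9.58e-05, and adjusted p = 0.322 with an estimated correlation). Microglia and macrophage markers rose in 9 of 15 cases (adjusted p = 0.000634, and adjusted p = 0.62 with an estimated correlation). The SHH list had 3 of 16 members lower (Gli1, Sfrp1 −2.72 ± 0.50 and Boc −1.39 ± 0.33) and 1 higher. The 1 that rose was Mycn (7.42 ± 0.10), through the probe set that was high with every vector. With it included, the list had a median of 0.17 and a mean of 0.27 while its test pointed down (adjusted p = 0.919). In all 1063 genes were called, 626 higher and 437 lower in Mycn tumours, and 1692 against the Ptch1-heterozygous model alone. Calls were lost for Gli1 (−0.89) and Barhl1 (−0.86) with array weights and for both (−0.78 and −0.78) without the 5 arrays that stand apart. Gli1 was not called with the GFP vector alone on the Mycn side (−1.08). Calls also ended for the p53 list (adjusted p = 0.0959), Cdkn1a (−0.73) and Eda2r (−0.49) against the Trp53-floxed model alone, and for the microglia list against the Ptch1-heterozygous model alone (adjusted p = 0.0585) or with the mRFP vector alone (adjusted p = 0.461).

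Wnt tumours (n = 3), which carry a stabilised Ctnnb1 allele, were compared with the mean of the other tumour classes. Of 14 measured WNT pathway and target genes 13 rose (adjusted p = 7.01e-07, and adjusted p = 0.14 with an estimated correlation). Wif1, a secreted WNT inhibitor, was at 5.21 ± 0.95, Tnfrsf19 at 4.06 ± 0.54 and Axin2, a feedback inhibitor, at 3.24 ± 0.43. These standard errors use the spread pooled over the 51 one-cycle arrays. Within the 3 Wnt arrays the SD was 2.88 for Wif1, 3.31 for Tnfrsf19 and 2.67 for Axin2, so these arrays differed widely. Granule lineage genes fell in 12 of 14 cases and rose in 1 (adjusted p = 2.81e-06, and adjusted p = 0.14 with an estimated correlation). The falls were led by the helix-loop-helix genes Nhlh2 (−5.89 ± 0.48) and Nhlh1 (−5.53 ± 0.49), with Atoh1 at −3.98 ± 0.76. Ribosome biogenesis genes fell in 17 of 22 cases (Nop56, a nucleolar protein, −2.55 ± 0.12; adjusted p = 1.15e-15, and adjusted p = 0.0212 with an estimated correlation). The other side includes Myc and Mycn tumours, whose medians of this list against control cells were 1.35 and 0.89. For Shh-type tumours that median was 0.25. Part of the fall may thus lie in the tumours with vectors, and Wnt tumours were not compared with control cells. Cell cycle genes fell in 17 of 19 (Birc5, survivin, −1.70 ± 0.13; adjusted p = 3.7e-12, and adjusted p = 0.0482 with an estimated correlation). Beside these lists, the signal at the 3' end minus that at the 5' end of the Gapdh control transcript averaged 2.28 in Wnt tumours and at most 0.494 in the other one-cycle groups, a sign of RNA quality that moved with the class. Dissociation and stress genes fell in 6 of 12 cases (Junb −2.22 ± 0.51; adjusted p = 0.0475, and adjusted p = 0.868 with an estimated correlation). Markers of cerebellar GABAergic neurons rose in 3 of 8 cases (adjusted p = 0.00771, and adjusted p = 0.14 with an estimated correlation). Among them Car8, a carbonic anhydrase of Purkinje cells, was at 4.65 ± 0.49. Within the 3 Wnt arrays the SD was 1.38 for Car8, 3.07 for Calb1 and 2.51 for Pcp2. Choroid plexus and ependymal markers rose in 4 of 8, with Kcnj13, a potassium channel, at 4.13 ± 0.18 (adjusted p = 0.0325, and adjusted p = 0.14 with an estimated correlation). The largest rises were A2m, a protease inhibitor of plasma (7.32 ± 0.51), Aldh1a1, a retinal dehydrogenase (6.79 ± 0.54), and Sulf1, a heparan sulfatase (6.08 ± 0.42). Falls included Insm1, a neuroendocrine transcription factor (−5.34 ± 0.40). Gli1 fell by −2.35 ± 0.58. Cdkn2c was higher by 3.27 ± 0.40, but the tumours of all other classes are labelled Cdkn2c-null and the Wnt tumours are not. This difference is therefore not read as a rise of Cdkn2c in Wnt tumours. Ctnnb1 was not called with the probe set chosen (0.10 ± 0.10). Its most variable probe set was lower by −1.94 ± 0.25. The library labelled Wnt replicate 2 had Axin2 at 7.17, against 11.11 and 12.26 in the others, while control cells had 7.82 ± 0.20 (SD, n = 4). In all 3573 genes were called, 1900 higher and 1673 lower, and 3752 without that library, of which 3073 were shared. The titles of the Wnt arrays carry another prefix than all others, so handling and tumour class cannot be told apart. The choroid plexus list did not pass after quantile normalization (adjusted p = 0.0534). The stress list did not pass without Wnt replicate 1 (adjusted p = 0.124) or 2 (adjusted p = 0.0542), nor (adjusted p = 0.0504 to 0.0557) without replicate 1, 2, 3, 4, 5 or 7 of the Trp53-floxed Shh model, 1, 2, 11 or 14 of the mouse Myc tumours, 3 or 4 of the Mycn mRFP tumours or 5, 6 or 7 of the Mycn GFP tumours. It also did not pass with the filter on dim probe sets (adjusted p = 0.210), the mean of probe sets (adjusted p = 0.0699), the most variable one (adjusted p = 0.120), median centring (adjusted p = 0.0505) or equal weights for the models (adjusted p = 0.0536), or without the 5 arrays that stand apart (adjusted p = 0.0618).

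Myc tumours were compared with control cells (n = 4). Ribosome biogenesis and MYC target genes rose in 15 of 22 cases, with Srm at 2.97 ± 0.16 (adjusted p = 4.57e-17, and adjusted p = 0.0132 with an estimated correlation). Glycolysis genes rose in 11 of 13, with Pdk1 at 3.63 ± 0.32 and Pfkl, a phosphofructokinase, at 3.04 ± 0.31 (adjusted p = 1.55e-08, and adjusted p = 0.0308 with an estimated correlation). Granule lineage genes fell in 11 of 14 cases (Atoh1 −4.50 ± 0.71, Cntn2, an axonal adhesion molecule, −3.54 ± 0.49; adjusted p = 6.15e-08, and adjusted p = 0.0827 with an estimated correlation). Neuronal differentiation genes fell in 7 of 15 cases, 8 adjusted over the list alone (Syt1, a synaptic vesicle protein, −3.34 ± 0.43; adjusted p = 0.00144, and adjusted p = 0.645 with an estimated correlation). The largest falls were Skor1, a transcriptional corepressor (−7.21 ± 0.41), and Cadps2, a vesicle release factor (−6.08 ± 0.87). Myc rose by 2.82 ± 0.45 and Gli1 fell by −4.07 ± 0.54. The control cells were sorted and the tumours were not, and RNA quality by beta-actin differed with the groups (1.18 in control cells, 0.680 in mouse Myc tumours). Beside these lists microglia and macrophage markers rose in 12 of 15 cases (Ctss, cathepsin S, 4.27 ± 0.69; adjusted p = 0.000399, and adjusted p = 0.645 with an estimated correlation), and endothelial and mural markers in 9 of 10 (Pdgfrb, 5.06 ± 0.55; adjusted p = 0.000399, and adjusted p = 0.592 with an estimated correlation). In all 2946 genes were called, 1540 higher and 1406 lower.

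Mycn tumours were set against the same control cells. The Mycn side includes replicate 2 of the mRFP tumours and replicate 3 of the GFP tumours, which were low for neuronal differentiation genes. Neuronal differentiation genes fell in 14 of 15 cases (Syt1 −2.53 ± 0.45; adjusted p = 3.75e-06, and adjusted p = 0.182 with an estimated correlation). Granule lineage genes fell in 10 of 14, 11 adjusted over the list alone (Pax6, a transcription factor of the rhombic lip, −2.60 ± 0.52; adjusted p = 1.81e-05, and adjusted p = 0.182 with an estimated correlation). Atoh1 (0.13 ± 0.74) and Gli1 (−0.63 ± 0.57) were not called. Neural stem cell genes rose in 5 of 13 cases, with Id3 at 4.31 ± 0.54 and Hes1 at 2.04 ± 0.38 (adjusted p = 0.000368, and adjusted p = 0.115 with an estimated correlation). Astrocyte markers rose beside them in 5 of 7 cases (S100b 2.97 ± 0.84; adjusted p = 0.0329, and adjusted p = 0.303 with an estimated correlation). That list did not pass without replicate 2 of the GFP-vector tumours (adjusted p = 0.0545), with the filter on dim probe sets (adjusted p = 0.102), with the most variable probe set (adjusted p = 0.116) or with the mRFP vector alone (adjusted p = 0.363, S100b 1.72). Ribosome biogenesis genes rose in 9 of 22 cases (Srm 2.20 ± 0.16) and glycolysis genes in 9 of 13 (Slc2a1, a glucose transporter, 2.47 ± 0.35), each with adjusted p = 0.0351 with an estimated correlation. Markers of microglia rose in 14 of 15 cases (Ctss 5.20 ± 0.72), of endothelial and mural cells in 8 of 10 (Rgs5 6.06 ± 0.55) and of fibroblasts in 7 of 9 (Col3a1 6.19 ± 0.84), each with adjusted p = 0.182 with an estimated correlation. Interferon response genes rose beside them in 7 of 11 cases (Bst2, tetherin, 3.53 ± 0.50; adjusted p = 0.000368, and adjusted p = 0.368 with an estimated correlation). Cell cycle genes were lower as a list, with 0 of 19 called and a median of −0.45. The camera adjusted p was 0.00385, and 0.391 with an estimated correlation. In all 2155 genes were called, 1256 higher and 899 lower.

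Among Shh-type, Myc and Mycn tumours, the Shh-type ones had the fewest genes called against the control cells, 899, of which 493 were higher and 406 lower. Gli1 (0.96 ± 0.54), Atoh1 (0.73 ± 0.71) and Ptch1 (−2.45 ± 1.05) were not called. Skor1 fell by −6.15 ± 0.42 and Tfap2b, a transcription factor, by −4.58 ± 0.43, while Olig1, an oligodendrocyte lineage transcription factor, rose by 5.29 ± 1.06 and Hhip, a decoy receptor and target of SHH signalling, by 2.72 ± 0.54. The p53 target list was higher (3 of 12 called, Cdkn1a 1.59 ± 0.29; adjusted p = 0.000134, and adjusted p = 0.00715 with an estimated correlation). Ribosome biogenesis and MYC target genes were higher as a list with 1 of 22 called (adjusted p = 8.38e-06, and adjusted p = 0.229 with an estimated correlation). Glycolysis genes were higher as well, with 3 of 13 up and 1 down (Slc2a1 1.52 ± 0.34; adjusted p = 0.0384, and adjusted p = 0.488 with an estimated correlation). Cell cycle genes were lower as a list with 0 of 19 called by limma and a median of −0.30 (adjusted p = 0.00402, and adjusted p = 0.473 with an estimated correlation). Neuronal differentiation genes fell in 3 of 15 cases (Nefl, a neurofilament, −4.38 ± 0.73; adjusted p = 0.0127, and adjusted p = 0.569 with an estimated correlation). Granule lineage genes fell in 3 of 14 cases (Pax6 −1.80 ± 0.50; adjusted p = 0.0127, and adjusted p = 0.481 with an estimated correlation). Neural stem cell genes rose in 3 of 13 (Cd44, a cell surface glycoprotein, 3.05 ± 0.58; adjusted p = 0.00966, and adjusted p = 0.229 with an estimated correlation). Microglia markers rose beside them in 9 of 15 cases, 10 adjusted over the list alone (Ctss 4.37 ± 0.69; adjusted p = 3.09e-08, and adjusted p = 0.249 with an estimated correlation). Endothelial and mural markers rose in 6 of 10 (Rgs5 3.82 ± 0.53; adjusted p = 8.38e-06, and adjusted p = 0.229 with an estimated correlation). Astrocyte markers rose in 3 of 7, 4 adjusted over the list alone (Slc1a3, a glutamate transporter, 1.56 ± 0.29; adjusted p = 0.0036, and adjusted p = 0.229 with an estimated correlation). With the Trp53-floxed model alone Cdkn1a was not called (0.73), nor was it with the mean of its probe sets (0.87) or the most variable one (0.15). With the Ptch1-heterozygous model alone the granule list (adjusted p = 0.114), the cell cycle list (adjusted p = 0.141), the glycolysis list (adjusted p = 0.471, Slc2a1 0.75) and the stem cell, neuronal and endothelial lists (each adjusted p = 0.0656) did not pass. The glycolysis list did not pass either without replicate 4 (adjusted p = 0.0538), 5 (adjusted p = 0.0756) or 7 (adjusted p = 0.05003) of the Trp53-floxed model or replicate 2 of the control cells (adjusted p = 0.0566), nor with the filter on dim probe sets (adjusted p = 0.0727), the mean of probe sets (adjusted p = 0.0586) or the most variable one (adjusted p = 0.0690).

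**Figure D3:**
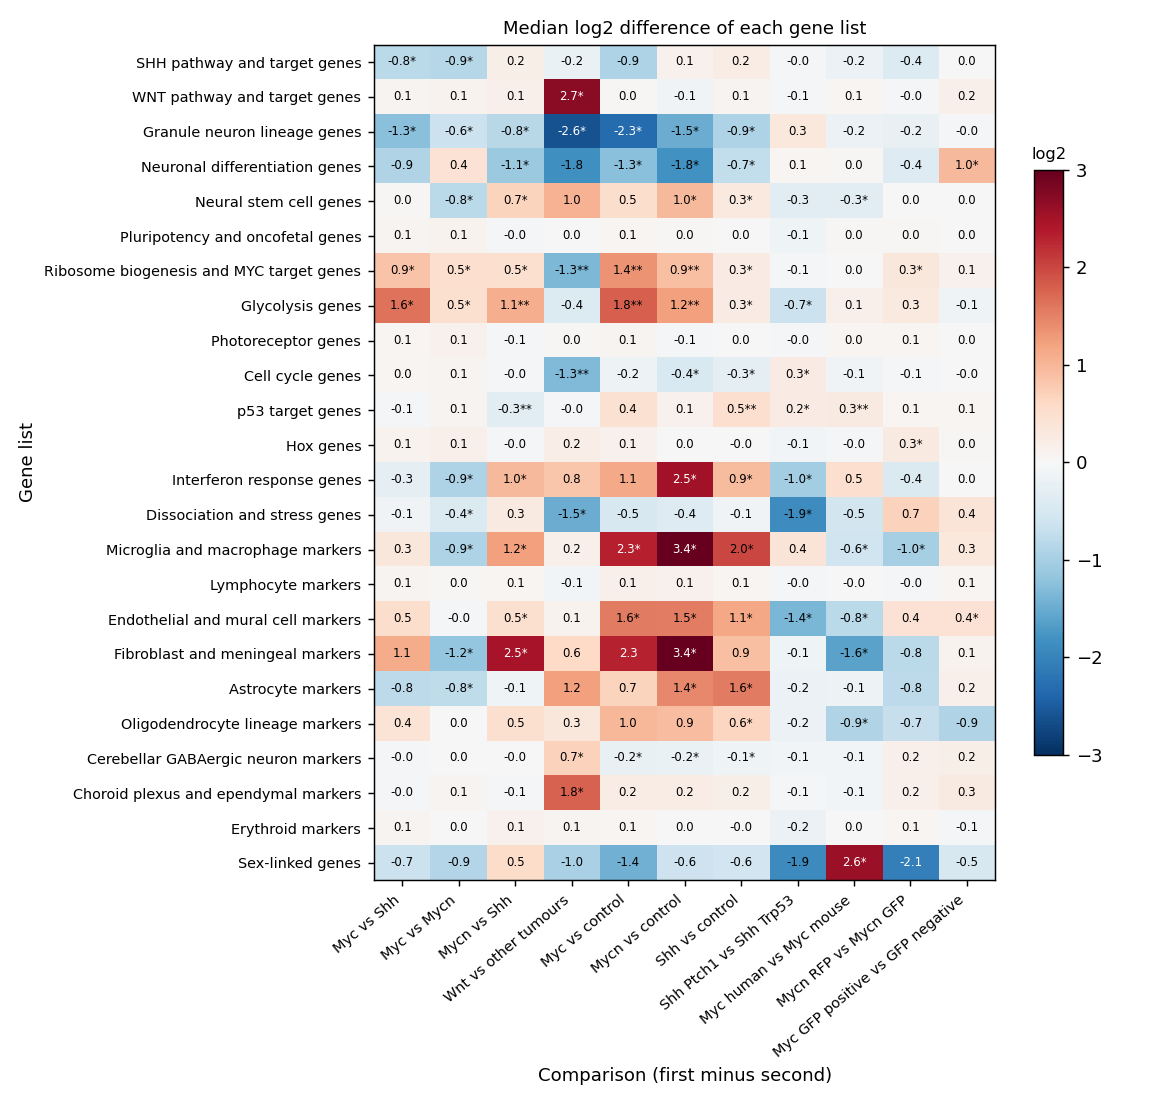
Median log2 difference of the measured members of each gene list (vertical axis) in each comparison (horizontal axis), in colour; 1 star marks an adjusted p under 0.05 at the preset correlation of 0.01 and 2 stars mark lists that also pass with an estimated correlation. The WNT list reaches 2.71 in Wnt tumours, and ribosome biogenesis genes reach 1.35 in Myc tumours against control cells.

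Both Shh models are labelled Cdkn2c-null, and the labels differ in Ptch1 heterozygosity or a floxed Trp53. Cdkn2c was nevertheless at 8.36 and 8.33 in the libraries labelled replicates 2 and 3 of the Ptch1-heterozygous model. Ptch1, the SHH receptor, was higher in the Ptch1-heterozygous model by 4.74 ± 0.94 (n = 8 and 8), with 11.51 ± 0.77 (SD) against 6.77 ± 3.50 (SD). Control cells were at 11.59 and the Trp53-floxed arrays ran from 4.09 to 12.39. With this probe set the difference thus lies in low values of the Trp53-floxed model. With another probe set the heterozygous model was at 7.81, the Trp53-floxed model at 5.54 and control cells at 5.47. Shtn1, a regulator of neuronal polarity, rose by 3.43 ± 0.74 and Myod1, a muscle transcription factor, by 2.99 ± 0.38, while Mdk, the growth factor midkine, fell by −4.18 ± 0.71 and Tecta, tectorin alpha, by −3.28 ± 0.37. P53 target genes went both ways (2 of 12 higher, 1 lower), with Eda2r at 1.75 ± 0.33 and Cdkn1a at 1.71 ± 0.26 (adjusted p = 0.0169, and adjusted p = 0.266 with an estimated correlation). Endothelial and mural markers fell in 8 of 10 cases, 9 adjusted over the list alone (Cldn5, a tight junction protein, −2.70 ± 0.49; adjusted p = 1.46e-06, and adjusted p = 0.433 with an estimated correlation). Interferon response genes fell in 4 of 11, 5 adjusted over the list alone (Usp18 −2.86 ± 0.70; adjusted p = 0.00957, and adjusted p = 0.832 with an estimated correlation). Dissociation and stress genes fell beside these lists in 10 of 12 cases, 11 adjusted over the list alone (Hspa1b, a heat shock protein, −2.81 ± 0.71; adjusted p = 8.08e-05, and adjusted p = 0.737 with an estimated correlation). RNA quality moved with the models, since the 3' minus 5' signal averaged 1.24 ± 0.31 (SD) against 0.71 ± 0.22 (SD) for beta-actin and 0.494 against 0.176 for Gapdh. Sex may differ between the models too. Sex-linked genes had 1 of 4 higher and 1 lower, 3 called when adjusted over the list alone (camera adjusted p = 0.744). In all 658 genes were called, 228 higher and 430 lower in the Ptch1-heterozygous model. The p53 list did not pass without replicate 8 of the Trp53-floxed model (adjusted p = 0.0613) or with array weights (adjusted p = 0.0505).

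Tumours with the human MYC vector (n = 3, GFP, cells without Math1-GFP) were compared with those with the mouse Myc vector (n = 14, mRFP, Math1-GFP cells), so vector, marker and mouse line differ together. Mouse Myc was lower by −3.69 ± 0.51, and it was high, at 10.34, in the library labelled as the third human MYC tumour. Rbm45, an RNA-binding protein, rose by 2.79 ± 0.42 and Ccl28, a chemokine, by 2.02 ± 0.25. The p53 target list was higher with both correlations (2 of 12 called, Cdkn1a 1.58 ± 0.33 and Sesn2, sestrin 2, 1.15 ± 0.20; adjusted p = 0.000777, and adjusted p = 0.0186 with an estimated correlation). Both sides are labelled as lacking Trp53, so this list is not read as p53 activity here. Fibroblast markers were lower as a list, with 0 of 9 called by limma over all genes and 6 adjusted over the list alone (adjusted p = 5.75e-05, and adjusted p = 0.298 with an estimated correlation). Other cell markers were lower beside them: endothelial and mural markers, with 0 of 10 called and 1 adjusted over the list alone (adjusted p = 9.89e-05, and adjusted p = 0.492 with an estimated correlation), and microglia (0 of 15; adjusted p = 0.0139) and oligodendrocyte markers (0 of 9; adjusted p = 0.0218), each with adjusted p = 0.856 with an estimated correlation. Sex-linked genes were higher as a list, with 0 of 4 called and 3 adjusted over the list alone, and Y-linked Eif2s3y at 3.59 ± 1.51 and Kdm5d at 2.71 ± 1.17 (adjusted p = 0.0444, and adjusted p = 0.260 with an estimated correlation). In all 73 genes were called, 53 higher and 20 lower, and 21 without replicate 2 of the human MYC tumours. The sex-linked list did not pass without replicate 1 (adjusted p = 0.127) or 3 (adjusted p = 0.0950) of them or replicate 1, 4, 6, 9, 10 or 12 of the mouse Myc tumours (adjusted p = 0.0501 to 0.0609), nor with the filter on dim probe sets (adjusted p = 0.0669) or the mean of probe sets (adjusted p = 0.0956). The oligodendrocyte list did not pass without replicate 1 (adjusted p = 0.0620) or 3 (adjusted p = 0.0760) of them, replicate 3 (adjusted p = 0.0583), 8 (adjusted p = 0.0623) or 14 (adjusted p = 0.0543) of the mouse Myc tumours or the arrays that stand apart (adjusted p = 0.576), nor with the filter (adjusted p = 0.0866). The microglia list did not pass without replicate 3 of the human MYC tumours (adjusted p = 0.215) or the arrays that stand apart (adjusted p = 0.108), nor with the filter (adjusted p = 0.0669). Sesn2 was not called without replicate 1 of the human MYC tumours (0.86), and Ccl28 was not called with the mean of its probe sets (0.72).

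Mycn tumours with the mRFP vector (n = 4, Math1-GFP cells) were compared with those with the GFP vector (n = 7, cells without Math1-GFP). Ankrd34b, an ankyrin repeat protein, was higher by 3.02 ± 0.48 and Rasd2, a small GTPase, by 2.92 ± 0.40, while Gbp2b, a guanylate-binding protein, was lower by −3.63 ± 0.62. Ribosome biogenesis genes were higher as a list with 0 of 22 called (adjusted p = 7.96e-06, and adjusted p = 0.523 with an estimated correlation). Microglia markers were lower with 0 of 15 called (adjusted p = 7.01e-05, and adjusted p = 0.745 with an estimated correlation). Of 4 sex-linked genes 1 fell, Y-linked Uty (−2.49 ± 0.69; camera adjusted p = 0.124 for the list), so sex may differ between these groups too. In all 231 genes were called, 118 higher and 113 lower, with 150 without replicate 2 of the mRFP tumours and 378 without replicate 3 of the GFP tumours. When only these groups were fitted, 38 genes were called and Gbp2b was not among them (−3.63, adjusted p = 0.108).

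GFP-positive and GFP-negative fractions of Myc tumours (n = 5 and 5) were compared with each other in an unpaired fit. The labels of these arrays do not say which construct the GFP comes from or which fractions share a tumour. Limma called 0 genes, with 932 at an unadjusted p under 0.05 and a lowest adjusted p of 0.947. Atoh1 differed by −0.11 ± 0.50 and Myc by −0.02 ± 0.60. Neuronal differentiation genes were higher in the positive fraction as a list, with 0 of 15 called and a median of 0.98 (adjusted p = 0.000962, and adjusted p = 0.863 with an estimated correlation). Endothelial and mural markers were also higher as a list, with 0 of 10 called and a median of 0.42 (adjusted p = 0.00316, and adjusted p = 0.863 with an estimated correlation). Without replicate 3 of the negative fractions, which had a mean of 11.27 over oligodendrocyte lineage markers, the neuronal list did not pass (adjusted p = 0.0666). The endothelial list did not pass without replicate 4 (adjusted p = 0.0823) or 5 (adjusted p = 0.0860) of the positive fractions or replicate 4 of the negative ones (adjusted p = 0.0940), nor with the filter on dim probe sets (adjusted p = 0.0677).

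**Figure D4:**
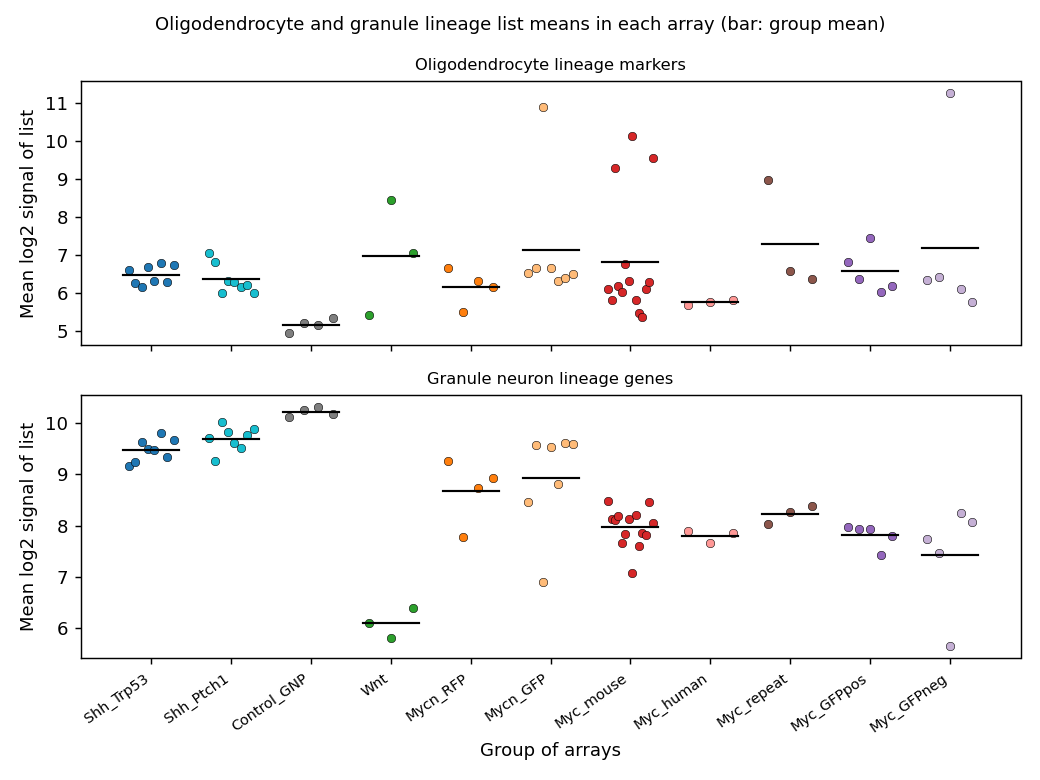
Mean log2 signal of the oligodendrocyte lineage markers and of the granule neuron lineage genes (vertical axes) in each array by group (horizontal axis), with group means as bars. Replicate 3 of the GFP-negative fractions stands at 11.27 for oligodendrocyte lineage markers and replicate 3 of the Mycn GFP-vector tumours at 10.90.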

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

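The tests of the Mycn probe set, of the chance overlap of the vector comparisons in both fits and of the oligodendrocyte lineage genes were chosen only after the results were seen. So was the test of the vector marker in its present form. The test of the Math1-GFP mice and the random splits were written before.

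Single arrays were searched for values far from the rest of their group with Dixon's test, over 8 genes and 24 list means in 7 groups of 4 to 8 arrays. Chance flags about 1 in 20 groups, or 11.2 of the 224 tests, and 21 were far from the others. Replicate 3 of the Mycn GFP-vector tumours stood apart for Atoh1 (4.95), Gli1 (3.92) and the list means of SHH pathway genes (7.42), granule lineage genes (6.90), neuronal differentiation genes (6.505) and oligodendrocyte lineage markers (10.90). Replicate 3 of the GFP-negative fractions stood apart for neuronal differentiation genes (5.80), interferon response genes (6.72), microglia and macrophage markers (9.32) and oligodendrocyte lineage markers (11.27). In the GFP-negative fractions replicate 2 stood apart for photoreceptor genes (4.57) and choroid plexus and ependymal markers (6.12). In the GFP-positive fractions replicate 5 stood apart for Ctnnb1 (12.37), replicate 3 for interferon response genes (6.14) and replicate 1 for microglia and macrophage markers (7.35). Replicate 2 of the Mycn mRFP-vector tumours was low for Atoh1 (6.66), and replicate 1 was apart for erythroid markers (4.10). In the Ptch1-heterozygous model replicate 7 stood apart for pluripotency and oncofetal genes (4.20) and erythroid markers (4.30). In the Trp53-floxed Shh model replicate 5 stood apart for choroid plexus and ependymal markers (6.07) and replicate 1 for erythroid markers (4.43). Among the 114 genes named by rank 95 of 798 such tests (11.9%) found an array far from the others.

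The control transcripts were outside the comparisons. Their signal at the 3' end minus that at the 5' end averaged 1.91 for beta-actin and 2.28 for Gapdh in Wnt tumours, while the highest control array had 1.39 and 0.325. The Wnt arrays are also the ones with another title prefix, so RNA quality, handling and tumour class cannot be told apart.

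The strongest probe set of Mycn was high in all 41 arrays of cells with a Myc or Mycn vector, 13 of them made with the other kit (12.53 to 14.32), and low in the 23 others (5.45 to 6.40). Another probe set of Mycn was lower in Myc than in Shh-type tumours by −5.89, which argues against a higher Mycn transcript in Myc tumours. The strongest probe set was higher in Mycn than in Shh-type tumours by 7.42 while Myc was lower by −1.54, which argues against cross-hybridisation with the Myc transcript. A sequence shared by the vectors may be read by this probe set, and the gap of 6.13 between arrays with and without a vector leaves it open, since that gap restates the pattern. Effects of carrying any vector on the gene itself were not tested.

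The comparisons of the vectors shared 11 genes, called in opposite directions in the Myc and the Mycn comparison and singled out after their values were seen (Bcl2l11, C920006O11Rik, Decr2, Galc, Hyls1, Myo5a, Pts, Rbm45, Spata5l1, Zfp874a and Zfp945), and 0 genes called in the same direction by limma. The Myc comparison was GFP minus mRFP vectors, and the Mycn comparison was mRFP minus GFP vectors. Opposite directions therefore mean that a gene differed the same way between mRFP tumours of Math1-GFP cells and the GFP-vector tumours. They do not mean opposite responses to Myc and Mycn. The larger of the one-sided Fisher's exact p for the overlap was 0.00028, which argues against chance overlap, but with only the groups compared in each fit (47 and 38 genes called) 3 of the 11 stayed called in opposite directions (Bcl2l11, Hyls1 and Rbm45, p = 4.77e-06), the other opposite direction shared 1 gene outside the 11 (p = 0.0142), Galc turned in the Mycn vectors with another probe set (−0.15), and so did Zfp945, then called lower in both (−2.17 and −2.12), the 1 gene shared in the same direction (p = 0.0128). The control arrays, from Math1-GFP mice without a vector, were on the side of the Math1-GFP tumours for 10 of the 11 genes, all but Myo5a. Galc and Zfp945 were among the 10 (90.9%, two-sided exact binomial p = 0.0117). That p takes the 11 genes as independent, though all were read from the same 4 control arrays, so it does not measure the spread between samples. A difference carried by the Math1-GFP mice is a candidate explanation that needs the control arrays on that side. An effect of the GFP vectors would put arrays without a vector there too, so a bound on the control arrays written before was wrong. The Shh models, without a vector and not labelled Math1-GFP, were on that side for 4 and 5 of the 11 genes, so the marker of the vectors stays open too.

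Oligodendrocyte lineage markers were high in 5 of 38 arrays of vector-carrying cells, with the 3 repeats left out (the highest, of replicate 3 of the mouse Myc tumours, had 8.96): replicates 3, 8 and 14 of the mouse Myc tumours, replicate 3 of the Mycn GFP-vector tumours and replicate 3 of the GFP-negative fractions. Their list means were 9.29, 10.1, 9.56, 10.9 and 11.3, against 5.36 to 7.46 in 33 others of both kits. Mog, a myelin protein, was at 6.09 to 9.26 against 2.88 to 4.14. Mobp, another list member, averaged 5.20 with an SD of 3.05 over the 5 GFP-positive arrays, with the probe set chosen in the fit of the fractions. By that spread Mobp was not low in every GFP-positive array. In replicate 3 of the Mycn GFP-vector tumours the probe set of Mycn that averaged 10.17 in Mycn tumours was 1.30 above the lowest of the 6 others. Granule genes of that array differed by a median of −2.54. Together these values argue against mixed-in cells as the cause of the lower granule genes in that array. In replicate 3 of the GFP-negative fractions, where the granule mean differed by −2.26, this stays open, since its strongest Mycn probe set was the lowest of its group (12.65). Mixed-in host oligodendrocytes may add the myelin transcripts: astrocyte markers differed by 2.20, 1.48 and 2.31 in the mouse Myc arrays but by −0.39 and 0.25 in the others, which leaves this open because oligodendrocytes without astrocytes would not raise them.

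Random splits of the arrays, 100 for each comparison with the real one included, asked whether as many genes would be called by chance. Only the real split, 1 of 100, called as many genes for Myc against Shh-type tumours (2264 genes, highest other split 624), Myc against Mycn (998 and 41), Mycn against Shh-type (1063 and 23), Wnt against the others (3573 and 1639), Myc against control (2946 and 1664), Mycn against control (2155 and 1013), Shh-type against control (899 and 58) and the Shh models (658 and 262). This argues against chance for these 8 counts. It takes the arrays as independent, although the labels do not say which come from separate animals. For the Myc vectors 2 of 100 splits called as many (73 and 80), the real one included. This is under the bound of 0.05 set before, but a random split called more genes than the real one, so chance is not excluded. Nor could chance be excluded for the Mycn vectors (231 and 478, 8 of 100). For the GFP fractions (0 and 1) the splits say nothing about chance, since with 0 genes called 100 of 100 splits must call as many.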

How the results depend on the processing

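The alternatives without doubtful arrays, without the 5 arrays that stand apart and without the strongest Mycn probe set, leaving out arrays of groups over 5, and with Myc and Mycn tumours matched by marker and mouse line, were chosen after seeing the data; all others were set before the data were examined.

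Of 12719 values of named genes under alternatives 12245 kept their direction and side of the threshold, 354 lost and 100 gained a call and 20 turned. With 1 array left out, 19197 of 19541 did, 281 lost and 63 gained a call. Gene lists did so in 3782 of 3923 cases (93 lost, 47 gained, 1 turned), and in 5727 of 5880 with 1 array left out. With an estimated correlation 10 of 81 list calls passed. The filter on dim probe sets left no lymphocyte gene in any comparison, and no photoreceptor or erythroid gene in the GFP fractions. The number of arrays limits precision.

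With the adjusted p alone the counts were 9808 (Myc vs Shh), 5962 (Myc vs Mycn), 5980 (Mycn vs Shh), 7929 (Wnt), 7226 (Myc vs control), 5446 (Mycn vs control), 2410 (Shh vs control), 3451 (Shh models), 161 (Myc vectors) and 672 (Mycn vectors), by construction since no size was asked for. The cause was not tested for 440 in Myc vs Mycn with the mRFP vector only and 396 with mRFP vectors on both sides, for 1692 in Mycn vs Shh with the Ptch1 model only, for 988, 132 and 356 with the most variable probe set (Shh models, Myc vectors, Mycn vectors), for 156 and 398 with array weights and for 47 and 38 with only the groups compared (Myc vectors, Mycn vectors).

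With 1 array left out the ranges were 2209 to 2302, 933 to 1096, 858 to 1177, 2960 to 3928, 2790 to 2989, 1892 to 2226, 729 to 947 and 575 to 734 for the first 8 comparisons. They were 21 (without human MYC replicate 2) to 90 for the Myc vectors, 150 (without mRFP replicate 2) to 378 (without GFP replicate 3) for the Mycn vectors, and 0 for the GFP fractions.

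Directions turned mostly for Mycn, because the alternative uses other probe sets: −5.94 and −5.89 (Myc vs Shh), −2.51, −4.45 and −3.56 (Myc vs Mycn), −2.33, −1.49 and −2.33 (Mycn vs Shh), −0.19, −5.79 and −5.75 (Myc vs control), −1.34 and −2.19 (Mycn vs control) and −1.84 and −2.26 (Mycn vectors). For the same reason Galc turned to −0.15 in the Mycn vectors and, in Wnt tumours, Ctnnb1 to −1.94, Msi1 to 0.34 and Mbp to 1.03 and 2.02. The endothelial list of Mycn vs Shh turned to −0.15 with the Trp53 model only, and the cause was not tested. The percent of genes higher moved by over 10 points to 55.8 (Myc vs Mycn), 42.0 (Shh vs control) and 64.6 (Mycn vectors) with the adjusted p alone, to 198 higher and 198 lower (Myc vs Mycn) with mRFP vectors on both sides, to 48.8 (Shh models) with the most variable probe set and to 59.0 (Myc vectors) with array weights.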

Other observations

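The 3 repeats of Myc tumours with the other kit correlated with their originals at 0.995 to 0.997. In the deposited values the kits were made equal on average, so the kits were not compared.

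Other gene lists had members called in 1 or both directions between Myc and Shh-type tumours without an adjusted p that passed for the list. Neuronal differentiation genes had 2 of 15 higher and 7 lower (adjusted p = 0.116), and p53 target genes 3 of 12 lower (adjusted p = 0.469). WNT pathway and target genes had 3 of 14 higher and 4 lower, with a median of 0.09, a mean of −0.33 and a test that pointed down (adjusted p = 0.773). Neural stem cell genes had 3 of 13 higher and 3 lower, with a median of 0.04, a mean of −0.08 and a test that pointed down (adjusted p = 0.798). Astrocyte markers had 1 of 7 higher and 2 lower (adjusted p = 0.305), endothelial and mural markers 2 of 10 higher (adjusted p = 0.409), dissociation and stress genes 2 of 12 lower (adjusted p = 0.674) and interferon response genes 1 of 11 higher (adjusted p = 0.798). In cerebellar GABAergic neuron markers 1 of 8 fell (adjusted p = 0.798), in choroid plexus and ependymal markers 1 of 8 (adjusted p = 0.773).

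Limma called 0 of 15 microglia and macrophage markers (adjusted p = 0.798), 0 of 11 pluripotency and oncofetal genes (adjusted p = 0.798), 0 of 10 Hox genes (adjusted p = 0.773), 0 of 9 lymphocyte markers (adjusted p = 0.798), 0 of 6 erythroid markers (adjusted p = 0.825) and 0 of 4 sex-linked genes (adjusted p = 0.773). In the same comparison 1 of 12 photoreceptor genes fell, with a median of 0.07, a mean of −0.15 and a test that pointed up (adjusted p = 0.987), and oligodendrocyte lineage markers had 1 of 9 higher and 1 lower (adjusted p = 0.987).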
